A study of Mus musculus with 72 samples.

How the data were processed

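RNA was sequenced from the left cortex, the left striatum and the right cerebellum of 24 male mice, per the labels. The animals were wild-type (wt) or carried the DYT1KI genotype, a knock-in at Tor1a, the gene behind the early-onset dystonia that the series title calls DYT-TOR1A. In each genotype the right sciatic nerve was crushed for 1 minute at 12 weeks of age or the animals were naive, and the labels date all tissue to 12 weeks post injury. The design holds 12 groups of 6 libraries, 72 libraries in all, and per the titles the same 24 animals gave all 3 tissues. The labels state RNA purification with miRNeasy columns, the mini kit for cerebellum and the micro kit for cortex and striatum, a stranded mRNA library kit, and that each sample was sequenced again for more depth. The libraries therefore allow comparisons within a tissue, and tissue and purification kit cannot be separated between cerebellum and the other regions.

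The deposited tables hold 1 raw read count per gene and library, per the file headers, with 45703 genes in each tissue's table. The authors' processing notes name cutadapt 4.6, STAR 2.7.2b, featureCounts 1.6.4, R 4.1.0, DESeq2 and the build GRCm38.p6; the DESeq2 version is not given in the sources used here. The strand setting, the handling of reads that map to several places and the merging of both sequencing runs are not given in the sources used here. The gene identifiers and sequence names in the deposited tables are those of the RefSeq annotation. The authors' comparison tables give a log2 fold change with its standard error, and whether these folds were shrunken is not stated. The same deposited tables give a p-value and an adjusted p-value per gene. All values below were computed from the deposited counts unless a sentence names the authors' tables.

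Counts per library (M, mega) ran from 14.42 to 24.22 M in cortex, 13.64 to 22.75 M in striatum and 10.66 to 22.01 M in cerebellum. No count was found in any library for 13012 genes in cortex, 13000 in striatum and 12215 in cerebellum. Reads carry no molecular identifiers as far as the labels state, so the errors given cover the spread between animals and not the number of molecules.

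Each tissue was fitted separately with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 17869 genes in cortex, 17820 in striatum and 18305 in cerebellum. Libraries were scaled by TMM and the quasi-likelihood test was run with robust dispersions on a model with 1 mean per group. For each tissue 5 contrasts were tested: DYT1KI against wt in naive animals, DYT1KI against wt in crushed animals, crush against naive in wt, crush against naive in DYT1KI, and the difference between the last pair (the interaction). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a contrast. Log2 fold changes are given with their standard error and CPM (counts scaled to library size by edgeR) with the SD over 6 animals. Tests are 2-sided.

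The test was tried on data simulated with 6 libraries per group and each tissue's dispersions. At a 2-fold change it recovered 46, 49 and 38 of 50 changed genes in cortex, striatum and cerebellum. At a 1.5-fold change it recovered 39, 37 and 28 of 50, and at a 1.25-fold change 43, 56 and 22 of 100. False calls made up 10 of 138, 7 of 149 and 4 of 92 calls.

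Before the data were examined, 35 gene lists, the contrasts, the rule for naming genes, the alternatives other than those said below to be added later, and the splits of the samples were fixed. The stress lists cover the integrated stress response and ATF4 targets, the unfolded protein response and endoplasmic reticulum (ER) chaperones, heat shock chaperones, glucocorticoid-responsive genes, inflammation and reactive glia, and the interferon response. The cell function lists cover translation initiation and elongation factors, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, cholesterol synthesis, the circadian clock, immediate early genes, torsin and the nuclear envelope, dystonia genes, plasticity and axon growth, and glutamatergic, GABAergic, and dopamine and acetylcholine signalling. The cell type and region lists cover medium spiny neurons, cortical excitatory neurons, interneurons, Purkinje cells, cerebellar granule cells, astrocytes and Bergmann glia, oligodendrocytes and myelin, oligodendrocyte precursors, microglia, endothelium and pericytes, choroid plexus and ependyma, meningeal fibroblasts, blood cells, thalamus, hippocampus, and the hypothalamus, pallidum and basal forebrain. A list of mitochondrially encoded transcripts matched none of the tables' gene names and is not analysed here. Of the other 34 lists, each with at least 5 measured members was tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 34 lists of a contrast. Camera asks whether a list's genes rank higher or lower than the other genes. The lists were also tested with a correlation estimated from the data, and with fry. Member counts are given over all genes and adjusted over the list alone. 3 further lists (brainstem markers, pituitary hormones, and abundant small structured RNAs) were added after the principal components had been seen.

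Genes were named by a fixed rule. Tor1a came first. In each pair of groups the 10 highest and 10 lowest log2 fold changes were taken among called genes with a mean of at least 1 CPM, leaving out predicted genes and clone names, and up to 5 each way in the interaction. Where fewer than 5 genes passed, the 5 with the smallest p are named. Up to 4 members with the smallest p are named for a list past its test, and up to 10 genes called in both genotypes. A few genes that this rule takes are not reported here. Genes outside this rule are said to have been chosen after their values were seen.

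The alternatives fixed beforehand were the DESeq2 1.42.0 Wald test, median-ratio scaling, no filter on low counts, a filter at a mean of 1 CPM, a fit to only the groups compared, the biological replicate number as a block, a term for animals numbered over 100, only animals over or only under 100, and the omission of outlying libraries. A library was called outlying when its median Spearman correlation with the others of its tissue lay over 3 scaled MAD below the median library. Leaving out single libraries had been planned only for groups of at most 5, and the groups hold 6. Chosen after seeing the data were leaving out each of the 24 libraries of a tissue, offsets that remove each library's trend against GC content and exon length (natural splines with 4 degrees of freedom), and scores of neighbouring-tissue markers as model terms. GC content was known for 92.1%, 92.2% and 92.5% of the tested genes of cortex, striatum and cerebellum, from the GENCODE M21 annotation. On simulated data with an added GC trend, these offsets took the unchanged genes called from 2308 to 3 in cortex, 3381 to 8 in striatum and 731 to 6 in cerebellum, and the changed genes called from 150 to 137, 156 to 130 and 113 to 77. A library's GC slope is the slope of log2 CPM (as deviation from the gene's mean in the tissue) on GC content per 10 percentage points. A list score is the mean over a list's genes of the standardised log2 CPM in the tissue. Differences of mean scores without single or outlying libraries, and without the pair of naive DYT1KI animals highest for heat shock, were also added after seeing the data; that pair was picked by its scores, so the fall of the heat shock difference without it is partly by construction.

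Animals are named by the number in their titles, written with an M before it. The numbers fall into M17 to M60 and M127 to M160, which the labels do not call batches. wt naive holds 1 animal from the lower range and 5 from the upper, and each other group 3 and 3. A fit for this split called 0 genes with edgeR in each tissue, with 1099, 1411 and 3000 genes at an unadjusted p under 0.05.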

Results

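Gene expression was measured in cortex, striatum and cerebellum of wt and DYT1KI mice. They were naive or 12 weeks after a crush of the right sciatic nerve, with 6 animals in each of the 12 groups. By its title the series asks how this genotype and a peripheral nerve injury act together in the brain. The median library held 18.32 M counts in cortex, 17.77 M in striatum and 18.5 M in cerebellum. Group means of depth ran from 16.74 ± 3.45 M (SD, n = 6) in crushed wt cerebellum to 20.26 ± 3.41 M in crushed DYT1KI cortex. Some libraries stood apart from the rest of their tissue. These were cortex DYT1KI crush M17 and M146, striatum DYT1KI crush M145, and cerebellum wt crush M19 and M28. Their median correlations with the other libraries lay -3.61, -3.19, -6.07, -3.59 and -19.83 scaled MAD from the median library. Throughout, log2 fold changes carry the standard error, and adjusted p are from edgeR for genes and from camera for lists. Some lists past camera lack a direction, as leaving out 1 library moved their score difference by over 1.5 times. The library kit is for mRNA, so counts of tRNAs, rRNAs, microRNA genes and small RNAs may follow RNA handling, which was not tested.

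**Figure D1:**
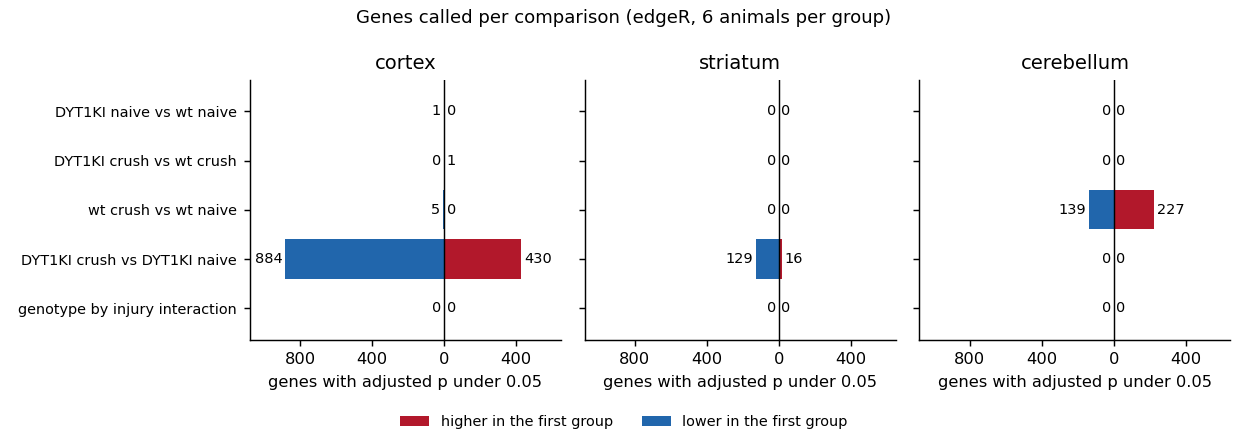
Numbers of genes called at an adjusted p under 0.05 in each tissue and comparison, with genes higher in the first-named group to the right (red) and lower ones to the left (blue). The longest bars belong to crush against naive DYT1KI cortex, with 430 genes up and 884 down.

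Tor1a (chromosome 2, 30960561 to 30967918 on the minus strand of GRCm38), which encodes the ER ATPase torsinA, was expressed at similar levels in all groups. In cortex it reached 23.3 ± 1.08 CPM (SD, n = 6) in naive wt, 25.3 ± 2.56 in crushed wt, 22.5 ± 1.45 in naive DYT1KI and 25.4 ± 1.84 in crushed DYT1KI. The same 4 groups had 21.2 ± 1.88, 21.8 ± 1.65, 19.8 ± 1.27 and 22.5 ± 1.28 CPM in striatum and 21.7 ± 2.26, 21.3 ± 3.95, 22.1 ± 1.07 and 20.2 ± 1.31 CPM in cerebellum. It was called in no comparison. Its smallest adjusted p was 0.0969, for crush against naive DYT1KI cortex (0.18 ± 0.07, 5 of 6 libraries). The sign of its genotype difference turned under other settings in cortex and cerebellum, and in naive striatum, so no direction is given. The allele is a knock-in, so these levels do not test the genotype labels.

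In naive cortex, where the comparison asks what the genotype does without injury, chaperone genes stood higher in DYT1KI and glial, meningeal and blood genes lower. Heat shock chaperones, which refold cytosolic proteins, had a median log2 fold change of 0.195 with 19 of 19 positive, and ER chaperones of the unfolded protein response 0.202 with 23 of 24 positive. Hsph1, a co-chaperone, had 0.30 ± 0.10 and the ER chaperone Dnajc3 0.31. Astrocyte markers lay lower in 18 of 18 genes at a median of -0.196, among them the glutamate transporter Slc1a3 (-0.29). Microglia markers lay lower in 20 of 20 genes at a median of -0.19, with the chemokine receptor Cx3cr1 at -0.23. Camera gave an adjusted p of 1.96e-08 for each chaperone list, 1.19e-09 for astrocyte and 2.16e-08 for microglia markers, each with adjusted p = 0.589 with an estimated correlation. DYT1KI naive M139 and M140, the highest animals for heat shock, carried much of the chaperone shift: without them the difference in mean score fell from 0.956 to 0.382 for heat shock and from 0.868 to 0.394 for ER chaperones. Without wt naive M160 the score differences were -0.691 for astrocyte and -0.585 for microglia markers, against -1.09 and -0.956 with all libraries. Meningeal fibroblast markers (-0.359, Col3a1 -0.79) and blood cell transcripts (-1.07, Hbb-bt -1.20) also ranked lower. Ribosomal, interferon, endothelial, myelin and GABAergic genes passed too, without a direction. These 11 lists passed camera, at adjusted p from 0.589 to 0.804 with an estimated correlation. The meningeal score difference went from -0.832 to -0.386 without M139 and M140. Adjusted over the list alone, 9 of 18 astrocyte, 3 of 18 meningeal and 5 of 6 blood genes were lower.

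No gene that the naming rule admits was called in that comparison. Serping1, a complement inhibitor (-0.85 ± 0.18), Myoc, a secreted glycoprotein (-1.38 ± 0.27; 25.5 ± 14.7 CPM in wt and 9.80 ± 2.19 in DYT1KI), and Rnase4, a secreted ribonuclease (-0.40 ± 0.09), had adjusted p = 0.263, and Gbgt1 (-0.93) and Cercam (-0.65) adjusted p = 0.329. Each lay on the same side in 6 of 6 DYT1KI libraries. The 1 gene that edgeR called was Oip5, a centromere gene with a mean under 1 CPM, chosen after its values were seen (-1.80 ± 0.29, adjusted p = 0.0255). DESeq2 called 4 genes, and 1622 genes had an unadjusted p under 0.05 against 893 by chance. The call was lost without wt naive M157, M158 or M159, without DYT1KI naive M27, M60, M139 or M140, with no filter or a filter at 1 CPM, with only the groups compared, with the replicate block and within either animal number range (0 genes in each case).

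In crushed cortex, 1 gene differed between the genotypes. Trub2, of the pseudouridine synthase family (chromosome 2, 29761223 to 29787671), was higher in DYT1KI, at 34.2 ± 1.95 CPM against 25.1 ± 2.97 CPM in wt (SD, n = 6). Its log2 fold change was 0.45 ± 0.07, with adjusted p = 0.0129 and 6 of 6 libraries higher. It lies in the same part of chromosome 2 as Tor1a. The next genes by p, Tnnt2 (-0.67), Pxylp1 (0.28), Pkd1l3 (-0.57) and Cercam (-0.48), did not pass (adjusted p = 1). DESeq2 also called 1 gene, and 364 genes had an unadjusted p under 0.05. Trub2 lost its call at adjusted p = 0.0522 without wt crush M28, 0.0783 without wt crush M29, 0.0502 without DYT1KI crush M17 and 0.0565 without DYT1KI crush M127, at 0.173 without both outlying libraries, at 0.189 with only the groups compared and at 0.842 and 0.999 in animals over and under 100.

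Among the lists in crushed cortex, markers of medium spiny neurons, the projection neurons of the striatum, ranked higher in DYT1KI in 21 of 21 genes at a median log2 fold change of 0.457. Drd2 (2.33 ± 0.96), the dopamine receptor, and Rxrg (2.03) had the smallest p of that list. Library DYT1KI crush M17 scored 3.82 for these markers, against -0.430 to -0.115 in the other 5 libraries of its group, and without it the score difference went from 0.589 to -0.0882. Immediate early genes, transcribed within minutes of neuronal activity, were higher in 29 of 29 genes at a median of 0.239, with Ier2 at 0.53 and Btg2 at 0.54, but their score difference of 0.377 was 0.109 without wt crush M19 and 0.724 without M17. No member of either list was called, over all genes or adjusted over the list alone. Camera gave adjusted p = 1.45e-05 and 0.00151, and adjusted p = 0.83 and 0.854 with an estimated correlation. GABAergic genes also ranked higher (0.0358), and inflammation (-0.12) and glucocorticoid-responsive genes (-0.0791, Plin4 -0.93) lower, the last with a score difference of -0.454, or -0.298 without wt crush M156. Oxidative phosphorylation, dopamine and acetylcholine, interferon, endothelial, circadian and ER chaperone genes passed without a direction. These 11 lists had adjusted p from 0.601 to 0.858 with an estimated correlation. Adjusted over the list alone, 2 glucocorticoid genes were lower.

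Nerve crush in wt cortex, which asks what the injury leaves behind after 12 weeks without the knock-in, lowered 5 genes. Rtl1, an imprinted gene derived from a retrotransposon, fell from 3.43 ± 0.708 to 1.46 ± 0.581 CPM (-1.22 ± 0.21, adjusted p = 0.0207). Mcc, which inhibits Wnt signalling, fell from 23.9 to 16.5 CPM (-0.54 ± 0.08, adjusted p = 0.0113). Nucks1 fell from 137 to 99.4 CPM (-0.46 ± 0.08, adjusted p = 0.0222). Rc3h2, an RNA-binding ubiquitin ligase, changed by -0.44 ± 0.08 (adjusted p = 0.0399) and Lrrc58 by -0.41 ± 0.07 (adjusted p = 0.0254). Each was below the naive mean in 6 of 6 crushed libraries. DESeq2 called 120 genes, 4 of these 5 among them, and 2449 genes had an unadjusted p under 0.05. With a term for the animal number range, Rtl1 and Mcc stayed called, and edgeR called 0 genes with only the groups compared, in animals over 100 or in animals under 100 (2257, 2517 and 1080 at an unadjusted p under 0.05).

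None of the 5 kept its call with every library left out in turn. Mcc lost it without wt crush M154 alone, and Rtl1, Nucks1, Lrrc58 and Rc3h2 kept it in 18, 16, 15 and 8 of 24 such fits. The count fell to 1 without wt naive M31 or M158 or wt crush M28 or M156, to 2 without wt naive M157, M159 or M160 or wt crush M19, and to 0 without wt crush M154. It rose to 23 without wt crush M128 and to 144 without wt crush M29.

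The lists of wt cortex moved by small amounts in many members. Cytosolic ribosomal proteins were higher after crush in 77 of 79 genes at a median of 0.171 (Rps9 0.23), oxidative phosphorylation genes in 67 of 76 at 0.104, and translation factors in 33 of 46 at 0.0689. By camera they had adjusted p = 1.12e-17, 1.34e-08 and 0.000969, each with adjusted p = 0.718 with an estimated correlation. ER chaperones (0.166), heat shock chaperones (0.149, Hsp90ab1 0.21), cholesterol synthesis (0.0957) and myelin genes (0.191) also ranked higher. Astrocyte markers were lower in 18 of 18 genes at -0.149, with the glutamate transporter Slc1a2 at -0.37, and GABAergic genes ranked lower at -0.0818. Score differences went from -0.659 to -0.258 for astrocyte genes without wt naive M160, 0.637 to 0.418 for oxidative phosphorylation without wt naive M31, 0.491 to 0.295 for cholesterol without wt crush M154 and 0.475 to 0.161 for myelin without wt crush M19. These 6 lists had the same adjusted p = 0.718 with an estimated correlation. Adjusted over the list alone, 3 translation factors, 1 cholesterol gene and 1 heat shock gene were higher, and 2 astrocyte genes and 1 GABAergic gene lower.

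The same comparison in DYT1KI cortex called 1314 genes, 430 up and 884 down, most by less than 2-fold (12 genes over 2-fold). The genes that rose most included Ier2, an immediate early gene (1.02 ± 0.31, adjusted p = 0.046, 5 of 6 libraries), Pdlim3, an actin-binding protein (0.82 ± 0.22), and Chil1, a secreted chitinase-like protein of reactive glia (10.5 ± 1.38 to 17.8 ± 2.77 CPM; 0.78 ± 0.19, adjusted p = 0.0189). Tmem53 rose by 0.75 ± 0.17 and Elmo3 by 0.73 ± 0.20. Zbtb11os1 (0.63), Gadd45g, a stress-response gene (0.62 ± 0.19, 5 of 6 libraries), Rpl37rt (0.52) and Gper1 (0.52 ± 0.16) rose too. The genes that fell most included the mitochondrial arginine tRNA TrnR (-1.63 ± 0.40), the long noncoding RNA Gt(ROSA)26Sor (6.79 ± 2.51 to 3.3 ± 0.879 CPM; -1.0 ± 0.20, adjusted p = 0.00925), Rtl1 (-0.88 ± 0.21) and Prrg1 (-0.87 ± 0.20). The microRNA genes Mir703 (-1.57), Mir1902 (-0.94) and Mir186 (-0.94), the zinc finger genes Zfp991 (-0.89) and Zfp992 (-0.77), and Cd200r4 (-0.87) fell too. All of these passed at adjusted p of at most 0.0495, and all but Ier2 and Gadd45g lay on the called side in 6 of 6 crushed libraries.

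All 5 genes called in wt cortex were also called, lower, in DYT1KI cortex, where chance would give 0.247 if genes were independent. Rc3h2 changed by -0.54 ± 0.08 (adjusted p = 0.00309), Nucks1 by -0.45 and Lrrc58 by -0.41 (both adjusted p = 0.00603), and Mcc by -0.43 (adjusted p = 0.00925). Of the 1314 genes called in DYT1KI, 1271 had the same sign in wt, 652 of them at an unadjusted p under 0.05.

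In DYT1KI cortex 49 of 79 ribosomal protein genes rose and none fell, at a median of 0.273, led by Rps20 (0.37 ± 0.08, adjusted p = 0.0104) and Rps9 (0.30). Adjusted over the list alone, 74 of the 79 were higher. Of 76 oxidative phosphorylation genes 17 rose, at a median of 0.166, among them Cox5b (0.35 ± 0.07, adjusted p = 0.00957) and Ndufa2 (0.42 ± 0.10); adjusted over the list alone 43 were higher and 2 lower. Of 29 immediate early genes 3 rose, Jun (0.45 ± 0.13), Ier2 and Gadd45g, with Btg2 at 1.04 (adjusted p = 0.0526), and adjusted over the list alone 5 were higher and 1 lower; their score difference of 0.605 was 0.364 without DYT1KI crush M146 and 0.952 without M17. Of 46 translation factors 5 rose and 1 fell, with Eif3k (0.27) and Eif3i (0.23) up and Eif4e down (-0.20). Adjusted over the list alone 16 were higher and 4 lower. Of 24 ER chaperone genes 3 fell, Canx (-0.28 ± 0.06), Dnajb9 (-0.39 ± 0.09) and Dnajc3 (-0.34 ± 0.11), the same 3 as adjusted over the list alone. The naive ER chaperone score averaged 0.473, against -0.164 after crush. Without DYT1KI naive M139 and M140 the naive score averaged -0.00025, so much of the list's fall rested on that pair. Of 24 GABAergic genes the receptor subunit Gabrb2 (-0.36) was among those that fell and the vesicular transporter Slc32a1 rose (0.20), and adjusted over the list alone 10 were lower and 1 higher. Camera gave adjusted p = 4.32e-28, 2.68e-14, 0.0127, 0.0106, 0.00665 and 0.0127 for these 6 lists, each with adjusted p = 0.882 with an estimated correlation.

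The DYT1KI cortex calls depended on the libraries used and moved with base composition. Called genes that rose had a median GC content of 54.5% and those that fell 41.1%, with median exon lengths of 1157.5 and 5552.5 bases. With GC and length offsets edgeR called 132 genes, 108 of them among the 1314, and of the 22 genes of the naming rule with a known GC content Rtl1, Rc3h2, Nucks1 and Mcc stayed called. EdgeR called 0 genes without the outlying DYT1KI crush M17 and M146, in animals over 100 and in animals under 100 (2568, 2890 and 2601 at an unadjusted p under 0.05), and 733 with no filter. The count was 548 without DYT1KI naive M133, 312 without DYT1KI naive M139, 429 without DYT1KI crush M17 and 288 without DYT1KI crush M146. Of the 24 genes the naming rule took 12 stayed called with any 1 of 24 libraries left out, namely Tmem53, Rpl37rt, Mir703, Gt(ROSA)26Sor, Mir1902, Zfp991, Rtl1, Prrg1, Rc3h2, Nucks1, Lrrc58 and Mcc. Among the others Gadd45g kept its call in 4, Ier2 in 6, Gper1 in 10, Zfp992 in 16, Pdlim3 in 17, Elmo3 in 18, Chil1 in 22, and TrnR and Cd200r4 in 23 of 24 such fits. DESeq2 called 1882 genes but only 12 of these 24, and of those stable to left-out libraries not Tmem53, Mir703, Mir1902, Zfp991 or Rtl1. It also left out TrnR, Pdlim3, Elmo3, Mir186, Cd200r4, Zfp992 and Zbtb11os1, and 4302 genes had an unadjusted p under 0.05.

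Whether crush acts differently in DYT1KI and wt cortex is the question of the interaction. No gene was called by edgeR (smallest adjusted p = 0.949) or DESeq2, and 770 had an unadjusted p under 0.05 where chance gives 893. The smallest p belonged to Sik2, a kinase of the AMPK family (-0.38 ± 0.10), Plin4, a lipid droplet protein (-1.51 ± 0.40), Slc35b2 (0.37), Fndc10 (0.33) and Myo1a (-0.85). The larger number of calls in DYT1KI than in wt is therefore not shown to be a difference between them. Among lists, ER chaperones were lower in DYT1KI relative to wt in 23 of 24 genes at a median of -0.266 (Xbp1 -0.38) and heat shock chaperones in 19 of 19 at -0.210 (Hsph1 -0.32). Astrocyte markers in 18 of 18 (0.135) and microglia markers in 20 of 20 (0.172, Cx3cr1 0.29) were higher. Without DYT1KI naive M139 and M140 the score difference went from -1.12 to -0.644 for ER and from -1.04 to -0.462 for heat shock chaperones, and without wt naive M160 from 0.857 to 0.455 for astrocyte and 0.789 to 0.418 for microglia markers. 10 lists passed camera, each with adjusted p = 0.924 with an estimated correlation.

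In naive striatum, a basal ganglia region studied in dystonia, DYT1KI animals again stood higher in chaperones and lower in blood transcripts. Heat shock chaperones were higher in 19 of 19 genes at a median of 0.236, with Hsp90ab1 at 0.21 and Chordc1 at 0.44. ER chaperones were higher in 22 of 24 at 0.220 (Syvn1 0.23), and adjusted over the list alone 10 were higher. Blood cell transcripts were lower in 5 of 6 at -1.27 (Alas2 -1.50, Hbb-bt -1.28), and the same number adjusted over the list alone. By camera they had adjusted p = 7.63e-11, 3.28e-09 and 3.81e-05, each with adjusted p = 0.308 with an estimated correlation. The chaperone shift rested largely on DYT1KI naive M139 and M140, without which the score difference fell from 1.03 to 0.34 for heat shock and from 0.845 to 0.291 for ER chaperones. Plasticity (0.0708, Vgf 0.40) and glutamatergic genes (0.0565) ranked higher, and GABAergic and hypothalamic, pallidal and basal forebrain genes passed without a direction, at adjusted p from 0.308 to 0.721 with an estimated correlation; adjusted over the list alone 2 plasticity genes were higher. No gene was called by edgeR, 4 were called by DESeq2 and 1163 had an unadjusted p under 0.05. The smallest adjusted p was 0.243, for Herc1, a large ubiquitin ligase (-0.21 ± 0.04), Dync2h1, a ciliary motor (-0.25 ± 0.05), Snrpa (0.19), Amigo2 (0.42) and Slc9a3r1 (0.26). Without DYT1KI naive M60 edgeR called 2 genes and without DYT1KI naive M133 1 gene.

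In crushed striatum, myelin markers were higher in DYT1KI in 24 of 24 genes at a median of 0.250, with Opalin, an oligodendrocyte membrane protein, at 0.42 ± 0.18. Camera gave adjusted p = 4.11e-10 and adjusted p = 0.913 with an estimated correlation, and no member was called adjusted over the list alone. Library DYT1KI crush M145, which stood apart, scored 2.7 for myelin and -1.74 for medium spiny neuron markers, and without it the myelin score difference went from 0.897 to 0.465. Translation (0.0339), oligodendrocyte precursor (0.101) and microglia genes (0.0444) also ranked higher and circadian clock genes lower (-0.0967, Per3 -0.31), and oxidative phosphorylation, ribosomal and astrocyte genes passed without a direction, each with adjusted p = 0.913 with an estimated correlation. EdgeR called no gene, DESeq2 called 4, and 1211 had an unadjusted p under 0.05. Ppp1r26, a phosphatase regulator (0.54 ± 0.09), and Trub2 (0.38 ± 0.07) had adjusted p = 0.0544, with 6 of 6 libraries higher, followed by the mitochondrial glycine tRNA TrnG (-0.46), Nt5dc2 (-0.47) and Kif9 (-0.47). The count became 1 without wt naive M138, wt crush M19 or M156, DYT1KI naive M133 or DYT1KI crush M26, and 2 without DYT1KI naive M60.

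Crush in wt striatum called no gene with edgeR and 4 with DESeq2, and 1632 genes had an unadjusted p under 0.05. Ptprb, an endothelial phosphatase (-0.36 ± 0.07), Il1rapl1, a synaptic adhesion protein (-0.41 ± 0.09), Herc1 (-0.20), Stub1 (0.16) and Cdnf, a neurotrophic factor (-0.66 ± 0.15), had adjusted p = 0.322. Ribosomal protein genes were higher in 79 of 79 at a median of 0.124 and oxidative phosphorylation genes in 74 of 76 at 0.0772. By camera they had adjusted p = 2.75e-21 and 2.62e-11, both with adjusted p = 0.648 with an estimated correlation. Heat shock chaperones ranked higher at 0.157 (Hspa1b 1.69 ± 0.66), ER chaperones at 0.156, ATF4 targets at 0.0643, hippocampal markers at 0.139 and cortical excitatory neuron markers at 0.384 (Neurod6 1.99). Score differences went from 0.46 to 0.253 for cortical markers without wt crush M28 and 0.659 to 0.425 for oxidative phosphorylation without wt crush M128. Translation and inflammation genes passed without a direction. Blood transcripts ranked lower at -1.07 (Alas2 -1.70). Over the 10 lists the adjusted p ran from 0.319 to 0.754 with an estimated correlation, and adjusted over the list alone 5 of 6 blood genes were lower and 1 cortical and 1 hippocampal marker higher.

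Crush in DYT1KI striatum lowered 129 genes and raised 16. The largest falls among named genes were in mitochondrial tRNAs and noncoding RNAs: TrnR (-1.75 ± 0.30, adjusted p = 0.0175), TrnI (-1.13 ± 0.17, adjusted p = 0.00365; 55.6 ± 12.0 to 25.4 ± 4.47 CPM), TrnG (-0.64 ± 0.10, adjusted p = 0.00365), Mir684-1 (-2.03) and Gt(ROSA)26Sor (-1.15 ± 0.23; 8.29 ± 2.22 to 3.71 ± 0.578 CPM). The protein-coding genes that fell most were Lrrc69 (-0.68), the synaptotagmin Syt10 (-0.61 ± 0.14), the engulfment adaptor Gulp1 (-0.60), the ubiquitin ligase Hectd2 (-0.53 ± 0.10, adjusted p = 0.0255) and Sh3bgrl (-0.50). Those that rose most were the troponin Tnnt2 (0.82 ± 0.20), Dcxr (0.50), the kinase Rps6ka1 (0.33), Kcne1l (0.31), Cabp7 (0.30), Rnaseh2a (0.30), Coro2a (0.27), Smdt1 (0.25), Washc3 (0.24) and Ndufb8 of respiratory complex I (0.24). All 20 passed at adjusted p of at most 0.0495 with 6 of 6 crushed libraries on the called side.

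The list changes in DYT1KI striatum were small and broad. Ribosomal protein genes were higher in 79 of 79 at a median of 0.186 (Rps14 0.29); none was called over all genes and 71 were adjusted over the list alone. Oxidative phosphorylation genes were higher in 75 of 76 at 0.127, 2 of them called, Ndufv1 (0.17 ± 0.04) and Ndufb8, and 37 adjusted over the list alone. Camera gave adjusted p = 1.47e-31 and 8.03e-22, both with adjusted p = 0.66 with an estimated correlation. Translation factors (0.0559, Eif3g 0.17, 5 higher adjusted over the list alone) ranked higher. ER chaperones (-0.131, Dnajc3 -0.25), heat shock chaperones (-0.0916, Chordc1 -0.51), GABAergic genes (-0.0643, Gabra2 -0.36, 3 lower adjusted over the list alone), and circadian genes (-0.0625, Clock -0.17) ranked lower. Without DYT1KI naive M139 and M140 the naive scores averaged -0.136 (ER) and -0.227 (heat shock), below -0.0799 and -0.0537 after crush. Myelin genes, medium spiny neuron markers and immediate early genes passed without a direction; without the outlying DYT1KI crush M145 the first went from 0.575 to 0.144 and the second from -0.443 to -0.145. Glutamatergic genes ranked lower at a median of -0.0369 (mean 0.0196), with 4 lower adjusted over the list alone. The 11 lists had adjusted p from 0.66 to 0.791 with an estimated correlation.

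The number of striatal calls changed with the libraries used more than their folds did. The count was 31 with no filter, 39 with only the groups compared, 6 with the replicate block, 551 with marker terms and 0 with edgeR in animals under 100 (1059 at an unadjusted p under 0.05). With GC and length offsets 3 genes were called, none of the 16 named genes with a known GC content among them, and called genes that rose had a median GC content of 56.3% and those that fell 40.5%. Without the outlying DYT1KI crush M145 the count was 8, with TrnR, TrnI and TrnG among the genes kept, while the median size of the called changes went from 0.319 to 0.306 (median SE 0.0734 to 0.0769). Of the 20 named genes only TrnI and TrnG stayed called with any 1 of 24 libraries left out; TrnR kept its call in 21 such fits, Hectd2 in 19, Gt(ROSA)26Sor in 16 and Tnnt2 in 5. The count was 230 without wt naive M138 and 435 without DYT1KI naive M39, and 3 without DYT1KI naive M133 or M139. It was 23 and 33 without wt naive M157 and M159, 21, 32, 42 and 72 without wt crush M29, M128, M154 and M156, and 76 and 13 without DYT1KI naive M60 and M140. It was 34, 8, 21, 29, 8 and 14 without DYT1KI crush M17, M26, M37, M127, M145 and M146. DESeq2 called 601 genes but only 12 of these 20, not TrnR, Mir684-1, Gt(ROSA)26Sor, Tnnt2, Dcxr, Kcne1l, Lrrc69 or Gulp1, and 2853 had an unadjusted p under 0.05. Of the called genes 134 had the same sign in wt, 46 at an unadjusted p under 0.05.

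The interaction in striatum called no gene with edgeR (smallest adjusted p = 0.84) or DESeq2, and 1049 genes had an unadjusted p under 0.05. Nt5dc2 (-0.72 ± 0.15), the cytokine Tnfsf9 (-1.45 ± 0.34), Cdnf (0.90 ± 0.22), the Ras pathway inhibitor Spred1 (-0.38) and Sik2 (-0.43) had the smallest p. Heat shock chaperones were lower in 19 of 19 at -0.242 and ER chaperones in 19 of 24 at -0.297 (Syvn1 -0.31), while blood transcripts ranked higher at 1.30 (Alas2 1.76) and myelin genes at 0.191. Without DYT1KI naive M139 and M140 the score difference went from -1.24 to -0.55 for heat shock and from -1.01 to -0.46 for ER chaperones, and without the outlying M145 from 0.765 to 0.334 for myelin. 9 lists passed camera, at adjusted p from 0.452 to 0.854 with an estimated correlation.

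In naive cerebellum, DYT1KI animals had higher chaperone and neuronal markers and lower myelin, microglial and blood markers. ER chaperones had a median of 0.281 (Sdf2l1 0.82, Hspa5 0.53), and heat shock chaperones were higher in 19 of 19 at 0.167 (Hspa8 0.24). The same animals M139 and M140 weighed most: without them the score difference fell from 0.776 to 0.203 for heat shock and from 0.723 to 0.227 for ER chaperones. Granule cell markers were higher in 19 of 19 at 0.221 (Gabra6 0.36) and Purkinje cell markers in 19 of 20 at 0.151 (Pcp2 0.21). Myelin markers were lower in 24 of 24 at -0.246 (Mag -0.31) and microglia markers in 20 of 20 at -0.223 (Itgam -0.33). Blood transcripts were lower in 10 of 10 at -2.13 (Hbb-bt -2.12, Hba-a1 -2.13), all 10 also adjusted over the list alone, and wt naive M158 scored 3.08 for them against -0.686 to 0.345 in the other 5 libraries of its group; without it the score difference went from -0.731 to -0.205. Brainstem markers, a list added later, scored -0.197 ± 0.282 against 0.448 ± 0.412 in wt (SD, n = 6), so a difference in the tissue dissected stays open. Dopamine and acetylcholine genes (-0.283), medium spiny neuron markers (-0.249) and cholesterol synthesis (-0.166) ranked lower and translation factors (0.0196) higher. The 11 lists had adjusted p from 0.56 to 0.835 with an estimated correlation; adjusted over the list alone 1 dopamine gene was lower. EdgeR and DESeq2 called no gene, and 1002 had an unadjusted p under 0.05. Cercam (-0.52 ± 0.11), Xylt1 (-0.43), Zfp119b (0.50), Trub2 (0.37) and Ddc, which makes dopamine and serotonin (-1.21 ± 0.30), had adjusted p = 0.879.

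In crushed cerebellum the genes with the smallest p between genotypes were abundant small RNAs, and ribosomal and oxidative phosphorylation genes ranked lower in DYT1KI. Bc1, a small neuronal RNA that represses translation (-4.30 ± 0.95), the signal recognition particle RNAs Rn7s1 (-2.55) and Rn7s2 (-2.53), the transcription regulator Rn7sk (-2.75) and the ephrin Efnb1 (0.42) had the smallest p (adjusted p = 0.365, 6 of 6 libraries). Bc1 turned to 0.303 without wt crush M19 and M28 and to 0.115 in animals over 100, and without that pair Rn7s1, Rn7s2 and Rn7sk were at -0.401, -0.390 and -0.655. Ribosomal protein genes were lower in DYT1KI in 79 of 79 at a median of -0.836 (Rpl39 -1.20), all 79 also adjusted over the list alone, and oxidative phosphorylation genes in 76 of 76 at -0.464 (Ndufb3 -0.80), 41 adjusted over the list alone. wt crush M28 and M19 scored 3.90 and 2.02 for ribosomal genes and 3.23 and 1.88 for small structured RNAs; the other 4 crushed wt libraries scored from -0.677 to -0.308 for ribosomal genes. Without both the score difference went from -1.12 to 0.0297 for ribosomal and from -0.945 to 0.138 for oxidative phosphorylation genes. Choroid plexus (0.609, Kl 0.79, Sostdc1 0.92) and meningeal markers (0.237) ranked higher, and without DYT1KI crush M37 their score differences went from 0.815 to 0.419 and from 0.581 to 0.141. The ribosomal, oxidative phosphorylation and choroid plexus lists had camera adjusted p = 6.26e-26, 2.16e-17 and 3.97e-06, each with adjusted p = 0.676 with an estimated correlation. The other 12 lists past camera, neuronal, glial and torsin genes among them, are given without a direction. The 16 lists had adjusted p from 0.676 to 0.903 with an estimated correlation. EdgeR called no gene, DESeq2 called 4, and 2118 had an unadjusted p under 0.05.

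**Figure D2:**
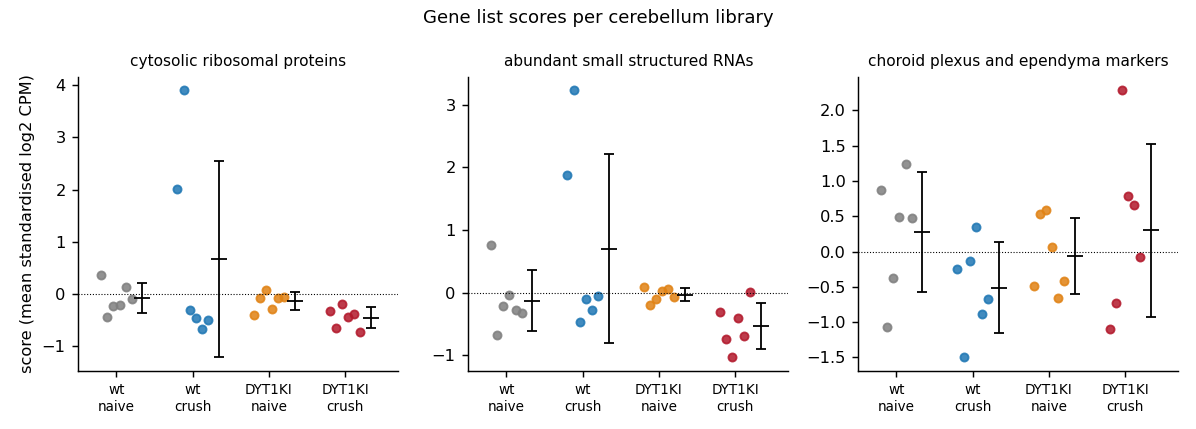
Scores (mean standardised log2 CPM) of 3 gene lists in the 24 cerebellum libraries, by group in order of animal number, with the mean and SD beside the points. wt crush M19 and M28 stand above their group for ribosomal genes, at 2.02 and 3.90.

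Crush in wt cerebellum called 366 genes, 227 of them up. Those that rose most were Bc1 (258 ± 35.7 to 6206 ± 11400 CPM; 4.59 ± 0.96, adjusted p = 0.0251, 3 of 6 libraries higher), the mitochondrial ribosomal RNAs mt-Rnr2 (1.81 ± 0.40) and mt-Rnr1 (1.67 ± 0.39), the mitochondrial tRNAs TrnF (1.94), TrnV (1.87), TrnG (1.68), TrnL1 (1.46), TrnM (1.24) and TrnW (1.09), and Kif5b, a kinesin motor of axonal transport (381 ± 19 to 1064 ± 1010 CPM; 1.48 ± 0.36, 5 of 6 libraries). Among those that fell most were Mapk15 (-1.01 ± 0.25), the collagen Col2a1 (-0.78), Klhl6 (-0.76), Rcn3 (-0.69), Vgf, a neuropeptide precursor (-0.66 ± 0.15), Ap5b1 (-0.65 ± 0.13), the Wnt antagonist Sfrp2 (-0.63), Lmcd1 (-0.58 ± 0.10, adjusted p = 0.0116) and the ephrin receptor Ephb3 (-0.56 ± 0.13). Each of the latter was below the naive mean in 6 of 6 crushed libraries. All 20 the naming rule took had adjusted p of at most 0.0487. Mitochondrial genes held 1.31 ± 1.17% of counts in crushed and 0.46 ± 0.07% in naive wt (SD, n = 6). M19 and M28 held 2.61% and 3.0%.

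In wt cerebellum 3 of 46 translation factors rose, Eif5 (0.42 ± 0.09), Eif4g2 (0.28) and Eif3m (0.32), and 8 were higher adjusted over the list alone (camera adjusted p = 0.00265). Ribosomal protein genes were higher in 79 of 79 at 0.646 (Rps24 1.03 ± 0.32), none called and 50 adjusted over the list alone (camera adjusted p = 3.42e-08), with wt crush M28 and M19 the only crushed wt libraries above 0. Both lists had adjusted p = 0.799 with an estimated correlation. Oxidative phosphorylation (0.318, Cycs 0.50) and heat shock genes (0.182) ranked higher. Without M19 and M28 the score difference went from 0.739 to -0.408 for ribosomal, 0.541 to -0.542 for oxidative phosphorylation, 0.519 to 0.0922 for translation and -0.693 to -0.102 for endothelial genes. Heat shock went from 0.564 to 0.367 without wt crush M156. Of the other lists, 1 of 33 ATF4 targets fell (Sesn2, -0.40 ± 0.08; 1 higher and 3 lower adjusted over the list alone), 1 of 28 dopamine and acetylcholine genes fell (Ache, which breaks down acetylcholine, -0.46 ± 0.11; 2 higher and 4 lower adjusted over the list alone) and 2 of 19 endothelial genes fell (Cldn5 -0.35, Slc2a1 -0.22; 1 higher and 2 lower adjusted over the list alone). Choroid plexus (-0.388, Ttr -0.59) and meningeal markers (-0.284) ranked lower. Over all 9 lists adjusted p ran from 0.799 to 0.833 with an estimated correlation.

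The cerebellar calls changed with the libraries used. Without wt crush M19 and M28 edgeR called 3153 genes, 317 of them among the 366, and of the 20 genes the naming rule took 12 stayed called, TrnF, TrnL1 and all 10 that fell, while the fold change of Bc1 became -0.01. EdgeR called 0 genes with GC and length offsets, with only the groups compared or in animals under 100, 1396 in animals over 100, 72 with marker terms and 37 with no filter. Called genes that rose had a median GC content of 42.1% and those that fell 58.6%. Lmcd1 alone among the 20 stayed called with any 1 library left out; Bc1 and Ap5b1 kept their calls in 20 of 24 such fits and Vgf in 19. The count was 11, 24 and 26 without wt naive M31, M159 and M160, 798 and 150 without wt naive M138 and M158, and 41, 551, 676, 197, 847 and 96 without wt crush M19, M28, M29, M128, M154 and M156. It was 241, 232, 241, 243 and 239 without DYT1KI naive M27, M39, M133, M139 and M140, and 241 without DYT1KI crush M127. With marker terms Vgf, Ap5b1 and Lmcd1 stayed called, and with the term for the animal number range 4 of the 20. DESeq2 called 1136 genes, 18 of the 20 among them, and 3501 had an unadjusted p under 0.05. Of the 366 genes 346 had the same sign in DYT1KI.

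Crush in DYT1KI cerebellum called no gene with edgeR and 103 with DESeq2, and 2296 genes had an unadjusted p under 0.05. Zfp945 (0.60 ± 0.12), Hdgfl2 (-0.26), the kinase Wnk3 (0.37), Cpox of heme synthesis (0.28) and Usp53 (0.40) had adjusted p = 0.192 with 6 of 6 libraries on 1 side. Oxidative phosphorylation (-0.115, Ndufs7 -0.28), ribosomal (-0.15), heat shock (-0.153) and ATF4 target genes (-0.0867) ranked lower, each with adjusted p = 0.98 with an estimated correlation. Without naive M139 and M140 the naive heat shock score averaged -0.206, below -0.112 after crush. With only the groups compared edgeR called 1321 genes, and in animals over 100 1 gene. Without wt crush M28, outside both groups but in the dispersion estimate, 2 genes were called, and without both outlying wt libraries 825.

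The interaction in cerebellum called no gene with edgeR (smallest adjusted p = 0.66) or DESeq2, and 1359 genes had an unadjusted p under 0.05. Ntn3, a netrin (0.68 ± 0.16), the kinase Ikbke (1.06 ± 0.27), Lmcd1 (0.53), Adamts2 (0.58) and the collagen receptor Ddr1 (0.41) had the smallest p. Ribosomal genes were lower in 79 of 79 at -0.782 and oxidative phosphorylation genes in 76 of 76 at -0.457, choroid plexus markers higher in 19 of 20 at 0.833, and heat shock genes lower in 18 of 19 at -0.319 (Ahsa1 -0.37). The ribosomal and oxidative phosphorylation differences came from wt crush M19 and M28: without them the score differences went from -1.06 to 0.0909 and from -0.936 to 0.147. Choroid plexus went from 1.15 to 0.756 without DYT1KI crush M37, and heat shock from -1.04 to -0.469 without DYT1KI naive M139 and M140. 13 lists passed camera, at adjusted p from 0.674 to 0.7 with an estimated correlation.

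Averaging the genotype effect over naive and crushed animals, a contrast added after the results were seen, called Trub2 (0.31 ± 0.05, adjusted p = 0.0189) and Cercam, an adhesion molecule of brain endothelium (-0.57 ± 0.10, adjusted p = 0.0486; 29845094 to 29882840), in cortex. In striatum it called Ppp1r26 (0.48 ± 0.07; 28446493 to 28455508), Trub2 (0.33 ± 0.05) and the predicted gene Gm36875 on chromosome 11 (-1.33), each at adjusted p = 0.00138. Trub2, Cercam and Ppp1r26 lie on chromosome 2 within 10 Mb of Tor1a, a window with 281 tested genes in cortex and 278 in striatum. That is 2 of 2 calls where chance gives 0.0315 (Fisher's exact p = 0.000246), and 2 of 3 where chance gives 0.0468 (Fisher's exact p = 0.00072). In cerebellum edgeR called none and 1397 genes had an unadjusted p under 0.05; Trub2 (0.34 ± 0.07) and Cercam (-0.39 ± 0.08) had the same signs at adjusted p = 0.489 and 0.615. DESeq2 was not run for this contrast.

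**Figure D3:**
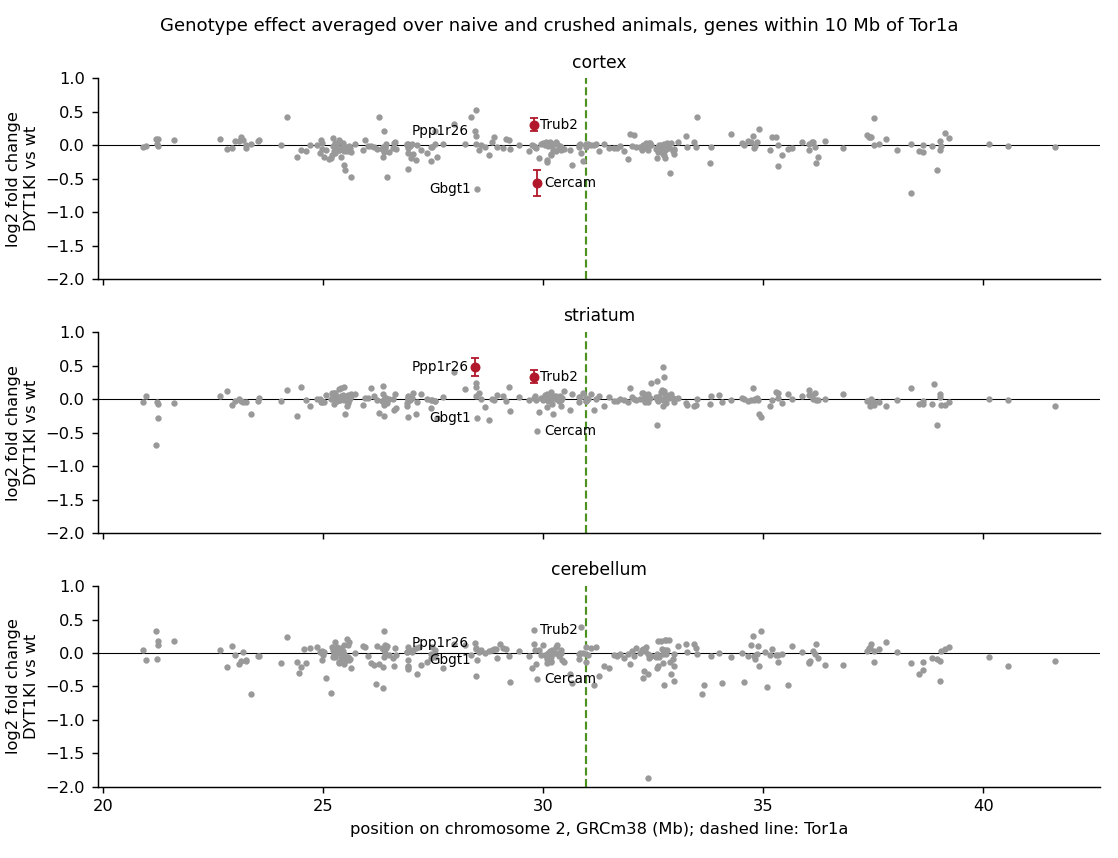
Log2 fold change of DYT1KI against wt, averaged over naive and crushed animals, for genes within 10 Mb of Tor1a on chromosome 2 (Mb, GRCm38). Red points with 95% confidence intervals are called genes, such as Trub2.

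GC slopes of the libraries moved with injury. In cortex the slope averaged -0.0353 ± 0.0584 in naive and 0.0689 ± 0.110 in crushed wt, and -0.0953 ± 0.0655 in naive and 0.0617 ± 0.0726 in crushed DYT1KI (SD, n = 6). In cerebellum it moved the other way, from 0.0882 ± 0.102 to -0.0746 ± 0.128 in wt and from 0.0681 ± 0.0375 to -0.0817 ± 0.0728 in DYT1KI. Over the 12 differences tested, the DYT1KI injury differences of 0.157 in cortex (exact permutation p = 0.00433) and -0.150 in cerebellum (exact permutation p = 0.00216) passed at adjusted p = 0.026 by permutation. Among animals over and under 100 these were 0.167 and 0.147 in cortex and -0.122 and -0.177 in cerebellum. The others did not pass: wt 0.104 in cortex (exact adjusted p = 0.134), wt -0.163 in cerebellum (exact adjusted p = 0.114), and 0.0727 in wt and 0.0681 in DYT1KI striatum (exact adjusted p = 0.0866 and 0.114).

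**Figure D4:**
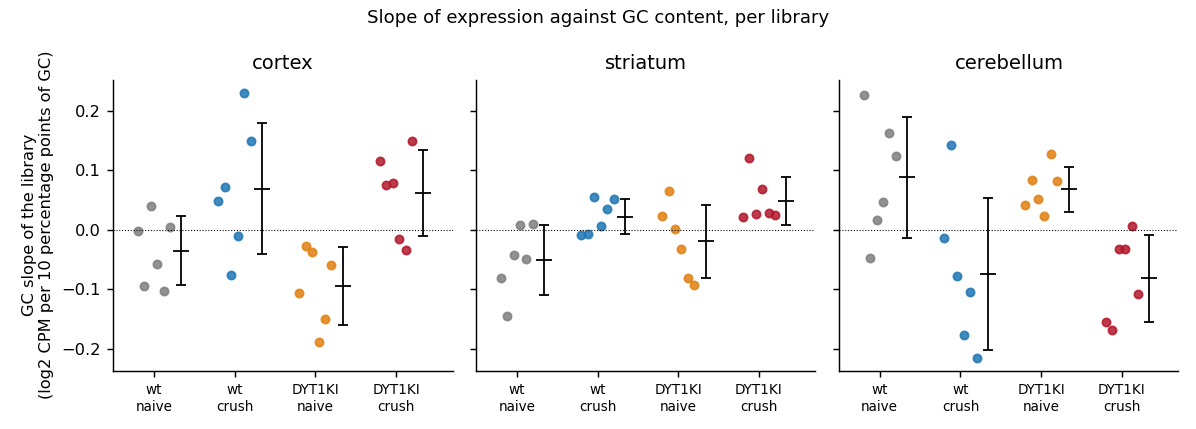
GC slope of each library (log2 CPM per 10 percentage points of GC content), by tissue and group in order of animal number, with the mean and SD beside the points. Crushed DYT1KI libraries lie above naive ones in cortex on average, 0.0617 against -0.0953, and below them in cerebellum.

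The heat shock chaperone score varied between animals in step across regions, a relation tested after it was noticed. As deviations from group means over 24 animals, Pearson's r was 0.906 between cortex and striatum, 0.851 between cortex and cerebellum and 0.887 between striatum and cerebellum. The permutation p were 1.00e-05, the smallest possible, 3.00e-05 and 7.00e-05, adjusted over 6 relations to 6.00e-05, 9.00e-05 and 0.00014, and Spearman's rho was 0.896, 0.823 and 0.860 (permutation p = 1.00e-05, 0.00025 and 0.0002). Without the 2 animals farthest from the median on the first region's score, r was 0.881, 0.818 and 0.840. Within animals numbered under 100 (n = 10) r was 0.881, 0.840 and 0.894, and within those over 100 (n = 14) 0.910, 0.870 and 0.895.

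**Figure D5:**
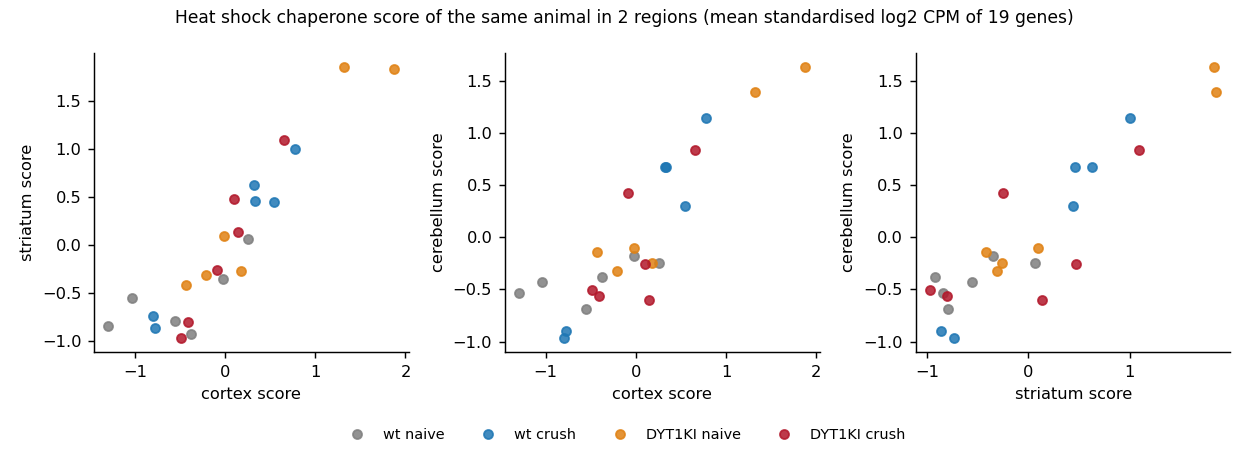
Heat shock chaperone score (mean standardised log2 CPM of 19 genes) of each animal in 1 region against another, coloured by group. Animals fall along a rising line in each panel, with r from 0.851 to 0.906 after group means were subtracted.

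Over the 510 list tests 83 passed camera upwards and 62 downwards, and none passed with an estimated correlation (smallest adjusted p = 0.308). Dystonia genes passed in no comparison (smallest adjusted p = 0.0587), nor did interneuron (0.235) or thalamic markers (0.0744). In the deposited tables of the authors, crush against naive DYT1KI has 1815 genes at an adjusted p under 0.05 in cortex (595 up) and 545 in striatum (144 up), and crush against naive wt has 1089 in cerebellum (703 up) and 114 in cortex (33 up).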

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

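Of the tests in this part, the GC and length offsets, the marker terms, the omission of single libraries, the medians without outlying libraries, the list scores without libraries, the count of genes flanking Tor1a and the group tests of GC slopes were chosen only after the results were seen; the splits of the samples and the omission of outlying libraries were chosen before.

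In 18 groups of 6 libraries, against 7.8 by chance over all groups tested (1 in 20), the highest or lowest value was separated from the rest by a gap beyond Dixon's critical value of 0.625. In cortex, wt crush M19 scored 0.489 for medium spiny neuron markers against -0.363 to -0.127 in its group, and DYT1KI crush M17 scored 3.819 for the same markers and 1.890 for brainstem markers. Choroid plexus markers scored 1.741 in cortex wt crush M28, 2.357 in DYT1KI naive M27 and 2.287 in DYT1KI crush M146, and blood transcripts 2.061 in wt crush M28. Cortex DYT1KI naive M39 had the lowest mitochondrial share of counts (0.490%) and rRNA share (0.477%) of its group, and DYT1KI naive M133 scored 1.763 for small structured RNAs. In striatum, wt naive M138 scored 1.163 for medium spiny neuron markers, wt crush M28 scored 1.172 for blood transcripts and DYT1KI naive M139 scored -1.312 for choroid plexus markers. DYT1KI naive M27 held 22.29 M counts in striatum, and DYT1KI crush M145 had 3.86% of its counts in 10 genes. In cerebellum, wt naive M138 scored -0.343 for brainstem markers, wt naive M158 scored 3.079 for blood transcripts, and Tor1a stood at 28.982 CPM in wt crush M28 against 17.649 to 21.061 CPM in the other 5.

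The injury effect differed between the genotypes, by camera on the interaction, for 32 lists, none of which passed with an estimated correlation (smallest adjusted p = 0.452). Median log2 differences (DYT1KI minus wt) in cortex were -0.266 for ER chaperones, 0.1 for ribosomal proteins, 0.0683 for oxidative phosphorylation, -0.0719 for cholesterol synthesis, -0.153 for glucocorticoid-responsive genes and -0.210 for heat shock chaperones. Cell type markers there differed by 0.358 for medium spiny neurons, 0.135 for astrocytes, 0.172 for microglia and 0.324 for meninges. In striatum they were -0.297 for ER chaperones, 0.0571 for ribosomal proteins, 0.0577 for oxidative phosphorylation, -0.071 for plasticity genes, -0.0755 for glutamatergic genes, -0.120 for the circadian clock, -0.242 for heat shock chaperones, 0.191 for myelin and 1.300 for blood. In cerebellum they were -0.236 for ER chaperones, -0.127 for translation factors, -0.782 for ribosomal proteins, -0.457 for oxidative phosphorylation, 0.0879 for glutamatergic, 0.376 for dopamine and acetylcholine, 0.169 for cholesterol synthesis and -0.319 for heat shock genes. Cell type markers there differed by 0.170 for myelin (mean 0.0324), 0.171 for oligodendrocyte precursors, 0.147 for endothelium, 0.833 for choroid plexus and 0.387 for meninges. The cerebellar ribosomal, oxidative phosphorylation and glutamatergic differences came from wt crush M19 and M28, without which the differences in mean score turned from -1.06 to 0.0909, -0.936 to 0.147 and 0.413 to -0.0719; translation factors went from -0.726 to -0.299 and endothelium from 0.67 to 0.0793, while myelin went from 0.566 to 1.17. Choroid plexus and meninges went from 1.15 to 0.756 and 0.949 to 0.509 without DYT1KI crush M37. The cortical medium spiny neuron difference came from DYT1KI crush M17 (0.51 to -0.166 without it). Without wt naive M160 those of ribosomal and oxidative phosphorylation genes went from 0.567 to 0.265 and 0.447 to 0.161, and cholesterol and glucocorticoid genes went from -0.489 to -0.293 and -0.463 to -0.307 without wt crush M154 and M156. In striatum oxidative phosphorylation went from 0.504 to 0.296 without DYT1KI crush M145, and ribosomal genes from 0.463 to 0.205 without DYT1KI naive M60. The chaperone differences shrank without DYT1KI naive M139 and M140, as given above. The cerebellar ER difference went from -0.421 to 0.0753.

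The injury effect on the GC slope differed between tissues, by exact permutation tests. Cortex minus cerebellum was 0.267 in wt (exact p = 0.0108) and 0.307 in DYT1KI (exact p = 0.00216), and striatum minus cerebellum 0.236 (exact p = 0.0152) and 0.218 (exact p = 0.00216).

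The first pattern is the injury calls graded by GC content and length in DYT1KI cortex and striatum and in wt cerebellum, with Spearman rho between fold change and GC content of 0.536, 0.286 and -0.483. With offsets that bring rho near 0, 108 cortex genes stayed called, 8.22% of those called. This argues against the trend as the whole cause for those 108. The rest stay open, as do the striatum and cerebellum calls, of which 3 (2.07%) and 0 stayed called. The median size of called changes went from 0.316 to 0.153 in cortex (median SE 0.0827 to 0.0631). It went from 0.319 to 0.219 in striatum (0.0734 to 0.0604) and 0.347 to 0.229 in cerebellum (0.0809 to 0.0834). So the changes shrank in part, and offsets could also remove biology graded by GC content. Genes still called with marker terms, 65.5%, 100% and 18.9%, argue against RNA of neighbouring tissue as their whole cause. Tissue that no term covers was not tested. The rest stay open, and in cerebellum the count went from 366 to 72. Slopes of regions of 1 animal correlated at r = 0.174, -0.143 and -0.147 (permutation p = 0.384, 0.603 and 0.478), which excludes nothing, so a state of the animal, library handling and an injury response within each region cannot be told apart.

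The second pattern is the pair of outlying wt crush libraries of cerebellum, M19 and M28, high in ribosomal and small structured RNAs. Without them the median change of the 366 called genes, in the direction called, went from 0.347 to 0.273 and the count went to 3153, which argues against them as the whole source of the changes, though not for Bc1, whose fold change went to -0.013. In cortex the median of the 1314 called genes went from 0.316 to 0.260 without DYT1KI crush M17 and M146, while the count went to 0 (median SE 0.0827 to 0.0892). A biological difference of these animals was not tested, and RNA quality values are not used here.

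The third pattern is the genotype calls beside Tor1a, in the genotype effect averaged over naive and crushed animals. Within 10 Mb lay 2 of 2 cortex calls and 2 of 3 striatum calls, in line with flanking sequence carried with the knock-in allele, and 0 cerebellum genes were called by edgeR, which leaves that tissue open (1397 genes at an unadjusted p under 0.05; DESeq2 was not run on averaged effects). Trub2 and Cercam had the same signs in all 3 tissues. An effect of the changed torsinA on these genes was not tested and stays open, as does a strain variant that alters the counting of reads.

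Each comparison had 100 random sample splits, the real one included. Only in some did few or no others call as many. For crush in DYT1KI cortex 1 split called as many (1314 genes, highest other 19), and 1 of 60 in a first draw (highest other 1). Chance is unlikely there. In striatum it was 1 (16 up, 129 down, highest other 97) and 2 of 60 (highest other about 1.6e2), so chance is not clearly excluded. For crush in wt cortex it was 3 of 100 (5 genes; highest other 1333) and 1 of 60 (highest other 4). For crush in wt cerebellum it was 2 of 100 (366 genes; highest other 4155) and 5 of 60 (highest other 6036), so the draws disagree and chance is not clearly excluded. The split with 4155 calls put wt crush M19, M28 and M29 together with wt naive M31, M159 and M160, and such splits point to a structure of the samples beside the injury. For genotype in cortex it was 5 of 100 in naive animals (1 gene; highest other 10) and 5 in crushed ones (1 gene; highest other 6), and 1 and 3 of 60 (highest other 0 and 118), so chance is not excluded in the larger draw. The other 9 comparisons called 0 genes with edgeR, so all 100 splits called as many; their highest other counts were 22 for the cortex interaction, 60, 4, 0 and 107 for striatum genotype (naive, crushed), wt injury and interaction, and 1, 2843, 0 and 1299 for cerebellum genotype (naive, crushed), DYT1KI injury and interaction. The first draw gave 1 for the first, 60, 8, 1 and 3 for striatum and 0, 2909, 0 and 0 for cerebellum. The first draw held fewer splits than the 100 called for.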

How the results depend on the processing

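GC and length offsets, marker terms and the omission of each library were chosen only after the results were seen. Values below are numbers of genes called, and the cause of a change was not tested except where fewer samples or genes are named. DESeq2 called 4 genes for naive genotype in cortex, 120 for wt injury in cortex, 4 each in striatum for naive genotype, crushed genotype and wt injury, 601 for DYT1KI injury in striatum, and 4, 1136 and 103 in cerebellum for crushed genotype, wt injury and DYT1KI injury. Median-ratio scaling gave 2 for crushed genotype in striatum. With no filter on low counts the counts were 0 for naive genotype and 733 for DYT1KI injury in cortex, 2 for crushed genotype and 31 for DYT1KI injury in striatum, and 37 for wt injury in cerebellum. A minimum mean of 1 CPM gave 0 for naive genotype in cortex and 2 for crushed genotype in striatum. Fits to only the groups compared, with fewer samples to estimate dispersions, gave 0 for naive genotype, crushed genotype and wt injury in cortex, 1 and 39 for crushed genotype and DYT1KI injury in striatum, and 1, 0 and 1321 for naive genotype, wt injury and DYT1KI injury in cerebellum. The replicate number as a block gave 0 for naive genotype in cortex, 1 and 6 for crushed genotype and DYT1KI injury in striatum, and 1 for crushed genotype in cerebellum. Same-numbered libraries correlated at a median r of 0.0327, 0.00633 and -0.00121 in cortex, striatum and cerebellum, so these numbers are not taken as pairs.

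Animals numbered over 100 gave 0 for each of the 4 comparisons of groups in cortex, 1 for wt injury in striatum, and 3, 1396 and 1 for naive genotype, wt injury and DYT1KI injury in cerebellum. Animals under 100 gave 0 for the same 4 in cortex, 0 for DYT1KI injury in striatum and 0 for wt injury in cerebellum. Both use fewer samples. A term for this range gave 2 for wt injury in cortex, 1 for crushed genotype in striatum and 1.5e2 (65 up, 81 down) for wt injury in cerebellum. Without outlying libraries the counts were 0 for crushed genotype and 0 for DYT1KI injury in cortex, 8 for DYT1KI injury in striatum, and 3153 and 825 for wt and DYT1KI injury in cerebellum. GC and length offsets gave 132 for DYT1KI injury in cortex, 2 and 3 for crushed genotype and DYT1KI injury in striatum, and 0 for wt injury in cerebellum. Marker terms gave 551 for DYT1KI injury in striatum and 72 for wt injury in cerebellum. With each library left out in turn, counts ran from 0 to 1 for naive and for crushed genotype, 0 to 144 for wt injury and 288 to 1763 for DYT1KI injury in cortex. They ran from 0 to 2 for naive and for crushed genotype, 0 to 0 for wt injury and 3 to 435 for DYT1KI injury in striatum. In cerebellum they were 0 to 0 for naive and for crushed genotype, 11 to 847 for wt injury and 0 to 2 for DYT1KI injury. The interaction had 0 genes by edgeR in each tissue under each setting tried and by DESeq2 (770, 1049 and 1359 genes at an unadjusted p under 0.05). Of the list tests past camera, 0 passed with an estimated correlation, 0 with directional fry and 17 with mixed fry.

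The sign of Tor1a turned in these cases, as log2 fold changes; ranges are the lowest and highest with single libraries left out. In cortex, naive genotype went to 0.016 with GC offsets, crushed genotype to -0.024 in animals over 100, -0.001 without outlying libraries and -0.013, -0.035, -0.012 and -0.006 without wt crush M19, wt crush M29, DYT1KI crush M26 and DYT1KI crush M127 (range -0.035 to 0.046), and the interaction to -0.012 with GC offsets. In striatum, naive genotype went to 0.032 in animals under 100, wt injury to -0.008 in animals over 100 and -0.03 with GC offsets, and the interaction to -0.014 in animals under 100. In cerebellum, naive genotype went to -0.013 with the range term, -0.175 in animals under 100 and -0.014 without wt naive M158 (range -0.014 to 0.076). Crushed genotype there went to 0.055 in animals over 100, 0.039 without outlying libraries, 0.065 with GC offsets and 0.036 without wt crush M28 (range -0.111 to 0.036). Injury there went to 0.005 (wt) and 0.01 (DYT1KI) with GC offsets, and in wt to 0.014 without wt naive M31 and 0.01 without wt crush M156 (range -0.134 to 0.014). The interaction there went to 0.007 without outlying libraries, 0.004 with GC offsets and 0.003 without wt crush M28 (range -0.140 to 0.003). Bc1 in cerebellum went to 0.115 and 0.303 for crushed genotype, and -0.012 and -0.013 for wt injury, in animals over 100 and without outlying libraries. Of 1636 values of named genes under other settings, 1168 kept direction and side of the threshold, 404 lost their call, 43 gained 1 and 21 turned sign, and with single libraries left out these were 2740, 578, 9 and 9 of 3336. Of the list tests past camera, 12 lost their call with the range term, 27 with GC offsets and 6 with the replicate block. At this depth, from 10.66 to 24.22 M counts per library, the smallest simulated changes were recovered for 43, 56 and 22 of 100 genes, so many changes of that size would be missed.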

Other observations

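The tests of heat shock scores and the overlaps of calls between tissues were chosen only after the results were seen, and the correlations of GC slopes between regions were chosen before.

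Genes that fell after crush in DYT1KI cortex tended to fall in DYT1KI striatum as well, although the libraries were made from different tissue of the same animals. Of 17046 genes tested in both, 1311 were called in cortex and 143 in striatum, 93 were lower in both (6.57 by chance), 2 higher in both (0.403 by chance) and 0 moved in opposite directions (4.02 by chance). Spearman rho between both sets of fold changes was 0.471. Cdc73 of the PAF1 transcription complex, Rc3h2, the splicing factors Mbnl1 and Srsf10, and Spred1 had some of the smallest ranks among the 93 (chosen after their values were seen). Both tissues share animals and the trend with GC content, so the overlap does not separate an injury response from that trend: with GC offsets 108 of the cortex calls and 3 of the striatum calls kept their call. Of 17053 genes tested in cortex and cerebellum, 1304 were called in DYT1KI cortex and 362 in wt cerebellum, 0 moved the same way and 78 in opposite directions (15 by chance), at rho = -0.271.

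Heat shock chaperone scores rose and fell together in the 3 regions of an animal. As deviations from group means, r was 0.906 between cortex and striatum and 0.851 and 0.887 between these and cerebellum. A candidate explanation is a state of the animal around the time of tissue collection, such as temperature or handling, since RNA preparation differed between cerebellum and the other regions. If so, group differences of this list may come from that state and not from genotype or injury, which was not tested. For GC slopes no such tie was shown (r = 0.174, -0.143 and -0.147), and that test leaves their origin open.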
